A study of Mus musculus with 28 samples.

How the data were processed

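RNA was measured on 28 one-colour mouse expression arrays with Affymetrix-style probe sets, hybridised with biotin-labelled RNA from testes of adult male C57BL/6 mice. Wild-type (WT) mice were compared with knockout (KO) mice lacking Ddx25, the gene of the gonadotropin-regulated testicular RNA helicase (GRTH), an RNA-binding enzyme of germ cells and Leydig cells. The 10 groups, taken from the sample titles, were WT and KO spermatocytes (4 arrays each), WT and KO round spermatids (3 each), WT and KO Leydig cells (2 each), WT and KO total polysome RNA (3 each), and polysome RNA recovered by immunoprecipitation (IP) with GRTH antibody (2) or with control IgG (2). Per the labels' protocols, polysomes came from sucrose gradients, cells were separated by centrifugal elutriation, RNA was extracted with Trizol, and 1 μg of it was labelled in a single step, or by a longer procedure with an additional labelling step for the IP samples. The free-text descriptions of 4 arrays (IgG IP 1, WT polysome 1 and 2, KO polysome 1) name another group than their titles, source names and genotype fields; the titles were followed. Nothing in the labels says that replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

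The deposited values are linear signal intensities for 45101 probe sets. Per the submitters' processing notes they came from GCOS, Affymetrix's array software; its version and settings are not given in the sources used here. On 24 arrays the authors had scaled the deposited intensities to a trimmed mean of 500 (a fraction of 0.02 trimmed at each end). The other 4 columns turned out to be unscaled, with trimmed means of 168 (WT polysome 1), 54.5 (WT polysome 2), 129.97 (KO polysome 1) and 29.8 (KO polysome 2). The plan made before the data were examined kept the authors' scale; because of these 4 columns, every array was instead rescaled to 500. Values were then transformed to log2(signal + 16), so fold changes understate the change of dim genes.

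Probe sets were named through the platform's annotation. Of them 34945 had 1 gene symbol, 932 had several and 9160 had none, and 64 control probe sets were left out. The Entrez identifiers of 34741 probe sets with 1 symbol were found in a current list of RefSeq genes, which changed 0 symbols. Each of the 18193 genes was represented by its probe set of highest mean log2 value over the 28 arrays; 9010 genes had several probe sets, and where a named gene's other probe set gave another direction this is stated. Each comparison tested the 9097 genes at or above the median mean signal of its own arrays.

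Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package (version 1.17.8), fitting the groups of each comparison alone, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The comparisons were KO against WT in polysome RNA, spermatocytes, round spermatids and Leydig cells, GRTH IP against IgG IP, WT round spermatids against WT spermatocytes, and the differences of the KO effect between round spermatids and spermatocytes and between polysome RNA and round spermatids. Effects are log2 differences ± SE and signals are means with SDs; every adjusted p given for a gene is limma's. Gene lists and cell-type markers fixed before the data were examined were tested with camera (a preset correlation of 0.01 between genes), adjusted over all lists and comparisons. No list call held when the correlation was estimated from the data. Every p given below as "with an estimated correlation" is likewise adjusted over all lists and comparisons. List medians are given relative to the median of all genes tested. Overlap of gene sets was tested with Fisher's exact test, two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.

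Genes were named by a rule fixed before the data were examined: up to 10 with the largest rise and 10 with the largest fall among those past the threshold whose groups do not overlap, Ddx25, and up to 4 members of each list with the smallest adjusted p; where fewer than 5 passed in a direction, the 5 with the smallest p were taken. The text names a part of these, chosen with their values in view.

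Samples with the same number deviated together from their group means: the correlations of deviations across genes were 0.436, 0.668 and 0.665 for the polysome pairs, 0.322, 0.28, 0.26 and 0.386 for spermatocytes, 0.247, 0.138 and 0.245 for round spermatids, and 0.261, 0.204 and 0.188 for WT round spermatids with WT spermatocytes. The data, not the labels, are the source of this pairing, and the fit with the replicate number as a block is given where it changes a call or moves a printed count by over 1.5 times in either direction of change. Within the germ cell groups, arrays 1 and 2 were closer to each other than to the rest, as were spermatocyte arrays 3 and 4: in WT spermatocytes the SD of log2 differences was 0.119 between arrays 1 and 2, 0.117 between 3 and 4, and 0.184 to 0.207 across. The 2 Leydig arrays of a genotype differed by SDs of 0.0845 (WT) and 0.0707 (KO), polysome arrays by 0.447 to 0.715, and the IP arrays by 0.939 (GRTH) and 1.12 (IgG).

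Counts of genes were recomputed with another offset (1 or 64), filter, normalization, probe-set choice, threshold, eBayes option and array weighting, with 1 fit over the 24 arrays labelled by the single-step method, with the replicate block, without the arrays of conflicting description and without each array in turn. Named genes were recomputed with both offsets, quantile normalization, another probe set, the fit over 24 arrays, the block and without each array. Lists were recomputed with an offset of 64, no filter, quantile normalization, the fit over 24 arrays, the block, fry and an estimated correlation, and without each array. Averages, blocks and subsets of near-identical arrays, the unscaled values, subsets of the polysome arrays and the overlap by group means were added after seeing the data. Leaving out an array of a group of 2 leaves 1 array, which is assumed to vary like the other group. The fits were tested on simulated data with 200 genes changed by known amounts among 9097. At a true log2 change of 1, 22.4% of changed genes were recovered for the polysome comparison, 98.5% for spermatocytes, 86.6% for round spermatids, 86.6% for Leydig cells, 97.0% for WT round spermatids against spermatocytes, 88.1% for the difference of effects between germ cells and 32.8% for that between polysome RNA and round spermatids. For the IP comparison 0% were recovered even at a log2 change of 2. The simulated noise was independent between arrays, unlike that of near-identical or same-numbered arrays. These shares therefore do not give the power over separate animals. The number of arrays limits the precision of all values.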

Results

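The 28 arrays profiled mouse testis RNA with and without Ddx25, from total polysomes, 3 elutriation-enriched cell fractions, and polysome RNA bound by GRTH antibody or control IgG. The series asks which polysomal testis transcripts depend on this helicase. Ratios of 3' to 5' actin probe sets lay between 1.57 and 2.09 on the 6 total polysome arrays, and between 3.81 and 12.8 on the 4 IP arrays, which were labelled by the longer procedure.

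Ddx25 itself was lower in every KO group. In total polysome RNA its signal was 16870 (SD 3710, n = 3) in WT and 822.1 (SD 233, n = 3) in KO, or 4.87% of WT. In spermatocytes it was 14910 (SD 1590, n = 4) and 3079 (SD 135, n = 4), or 20.7% of WT. Round spermatids had 16690 (SD 1550, n = 3) and 4234 (SD 366, n = 3), or 25.4%, and Leydig cells 14050 (SD 200, n = 2) and 3524 (SD 0.0355, n = 2), or 25.1%. In this order, the log2 changes were -4.35 ± 0.27 (adjusted p = 0.00017), -2.26 ± 0.08 (1.4e-07), -1.98 ± 0.10 (7.44e-06) and -1.99 ± 0.02 (2.38e-05). Whether the gene's single probe set lies within the deleted part is not given in the sources used here.

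**Figure D1:**
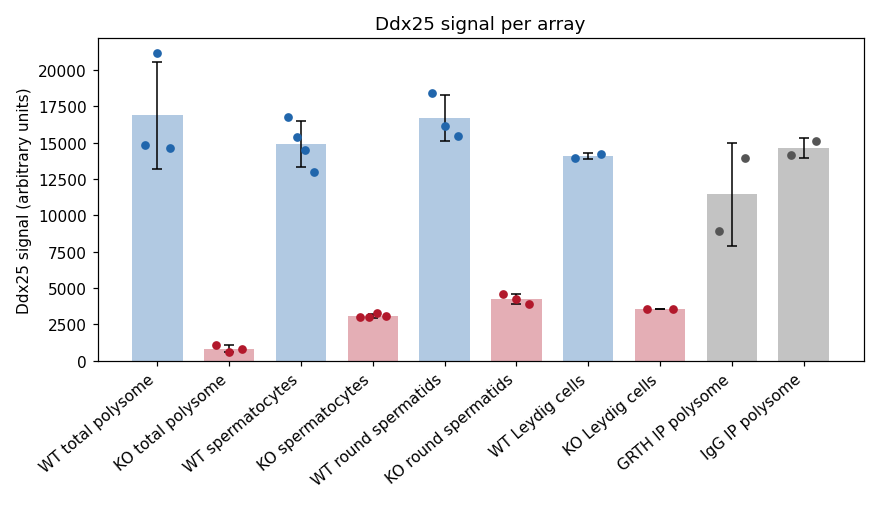
Ddx25 signal (arbitrary units, linear axis from 0) on each of the 28 arrays; bars are group means, error bars SDs and points arrays. The KO means lie between 822.1 and 4234, below every WT mean (14050 to 16870), and the GRTH IP and IgG IP means are 11450 and 14640.

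In KO total polysome RNA, transcripts of the last, shape-changing steps of sperm formation were far lower than in WT (n = 3 per genotype). Cabs1, a calcium-binding protein of the sperm tail, was 11.7-fold lower (log2 change -3.55 ± 0.22), and Prm3, a protamine-related gene, 11.3-fold lower (-3.50 ± 0.28). Tssk6, a kinase of spermatids, was 11.2-fold lower (-3.49 ± 0.34), and Oaz3, an antizyme of the polyamine pathway in spermatids, 11.1-fold lower (-3.47 ± 0.34). The adjusted p of these genes lay between 0.00017 and 0.00053. Among genes that rose, Aplp1, an amyloid precursor-like membrane protein, was 3.23-fold higher (1.69 ± 0.28, adjusted p = 0.00589), and Sdc4, a syndecan, 2.63-fold higher (1.39 ± 0.25, 0.00893).

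All 16 tested markers of elongating spermatids fell in KO polysome RNA (16 adjusted over the list alone). Their median was -2.80 relative to all genes (camera adjusted p = 8.94e-24, or p = 0.48 with an estimated correlation). They included Smcp, a protein of the sperm mitochondrial sheath (-3.22 ± 0.29), Spata3 (-3.17 ± 0.30) and Hmgb4, a chromatin protein (-2.59 ± 0.24). Of 12 genes for transition proteins, protamines and spermatid chromatin, 8 fell (8 adjusted over the list alone, adjusted p = 2.4e-07, or p = 0.48 with an estimated correlation). Among them were Tnp2, a transition protein (33710, SD 11600, in WT and 5997, SD 2320, in KO), and Hils1, a spermatid linker histone (-2.10 ± 0.27), and the block gave 1 higher beside the 8 lower. In the sperm flagellum list 15 of 33 genes fell, or 19 adjusted over the list alone (adjusted p = 5.25e-13, or p = 0.48 with an estimated correlation). Its kinase Tssk3 fell by 3.46 on the log2 scale. Ppp2r2b, a phosphatase subunit (-3.42 ± 0.33), H2al2a, a histone variant (-3.38 ± 0.28), and Lelp1 (-3.30 ± 0.29) were also among the 10 largest falls. So was Lrrc57 (-3.68 ± 0.27), whose other probe set read 0.03 (adjusted p = 0.963).

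Genes of sperm metabolism and protein turnover fell with them. In the energy metabolism list 6 of 22 fell (8 adjusted over the list alone, adjusted p = 0.00027, or p = 0.489 with an estimated correlation). They included Gapdhs, the glycolytic enzyme of sperm (20930, SD 12600, against 2759, SD 916), and Acsbg2, an acyl-CoA synthetase (-2.19 ± 0.27). Gpd2, a mitochondrial glycerol phosphate dehydrogenase, fell by 1.70 on the log2 scale, but its other probe set read 0.06 (adjusted p = 0.964). In the ubiquitin and proteasome list 10 of 42 fell, against 11 lower and 2 higher with the block (10 adjusted over the list alone, adjusted p = 0.00138, or p = 0.48 with an estimated correlation). The ubiquitin ligase Rnf133 was 9.70-fold lower (-3.28 ± 0.23) and Ubqlnl 8.47-fold lower (-3.08 ± 0.35). The conjugating enzyme Ube2j1 (-2.12 ± 0.21) and the ligase Rnf138 (-1.91 ± 0.21) also fell, while their other probe sets read -0.0043 (adjusted p = 0.995) and -0.15 (0.864).

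Smaller parts of other spermatid lists fell. Of the acrosome list, 2 of 25 fell, with 6 adjusted over the list alone and 10 with the replicate block (adjusted p = 0.000222, or p = 0.499 with an estimated correlation). These were Capza3, an actin-capping subunit (-2.52 ± 0.26), and Prss55, a serine protease (-1.55 ± 0.28). Round spermatid markers had 2 of 10 lower, with 3 adjusted over the list alone and 6 with the replicate block (adjusted p = 0.000165, or p = 0.48 with an estimated correlation). Cby2 (-2.51 ± 0.28) and the kinase Tssk2 (-2.13 ± 0.28) were the 2 that passed. Sperm ion transport had 2 of 11 lower, or 3 with the block (2 adjusted over the list alone, adjusted p = 0.0328, or p = 0.48 with an estimated correlation), among them the sodium pump subunit Atp1a4 (-2.01 ± 0.30).

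**Figure D2:**
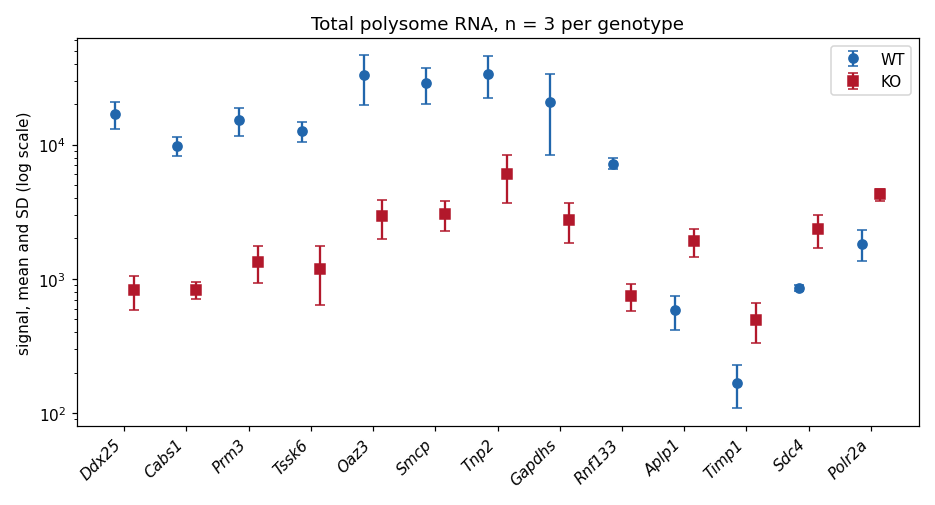
Signal of 13 genes in total polysome RNA (log axis), WT circles and KO squares with SDs, n = 3 per genotype. Ddx25 falls from 16870 to 822.1 and Cabs1 from 9825 to 824.4, while Aplp1 rises from 583.4 to 1899.

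Other lists held few changed genes. Of 31 spermatid regulators 3 fell (3 adjusted over the list alone, list adjusted p = 0.0828), among them the CREM coactivator Fhl5 (-2.44 ± 0.25) and the kinesin Kif17 (-1.51 ± 0.23). Another probe set of Kif17 read -0.89 (adjusted p = 0.18). Hspa1l, a testis heat shock protein (-2.64 ± 0.26), was 1 of 2 genes lower among 23 of the heat shock list (adjusted p = 0.964). Bcl2l14 (-2.35 ± 0.23) was the only one of 24 in the apoptosis list, and its other probe set read -0.70 (adjusted p = 0.208). Among 36 meiosis genes, Syce2, a synaptonemal complex protein, alone passed (-0.90 ± 0.19, adjusted p = 0.0234). The call of Syce2 was lost with quantile normalization (0.0718) and without WT array 1 (0.07) or 3 (0.0641) or each KO array (0.0596 to 0.105). Lipe, Aif1 and Actg2, listed for steroid-producing cells, macrophages and smooth muscle, fell as the spermatid genes did (-1.71 ± 0.28, -2.27 ± 0.30 and -1.76 ± 0.26). With the replicate block these lists held more genes, namely 1 higher and 6 lower (regulators), 5 and 4 (heat shock), 5 and 1 (apoptosis), 1 and 1 (meiosis), 8 and 2 (steroidogenesis), 4 and 1 (macrophages) and 3 and 1 (smooth muscle). The block also brought the steroidogenesis list past the threshold, from a camera adjusted p of 0.0969 to 0.0139 (without the block, p = 0.619 with an estimated correlation).

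Markers of Leydig and Sertoli cells leaned the other way without single genes passing. Leydig cell markers had 0 of 8 changed (0 adjusted over the list alone), against 7 higher with the replicate block. Their median was 0.76 relative to all genes (camera adjusted p = 0.00495, or p = 0.547 with an estimated correlation). Star, which moves cholesterol into mitochondria, read 1.05 ± 0.38 (limma adjusted p = 0.165, and 0.000552 with the block) and Hsd3b1, a steroid dehydrogenase, 1.12 ± 0.34 (0.104, and 0.000586 with the block). Fabp3, a fatty acid carrier, read 0.82 ± 0.28 (adjusted p = 0.144, with 0.00629 under the block and 0.0401 under quantile normalization).

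Sertoli cell markers had 0 of 15 changed, with 0 adjusted over the list alone and 8 with the block, and a median of 0.44 (adjusted p = 0.0177, or p = 0.641 with an estimated correlation). Gata4 read 1.24 ± 0.49 (0.211, and 0.000125 with the block), Cldn11 0.59 ± 0.26 (0.262, and 0.0295) and Cst12 0.56 ± 0.26 (0.276, and 0.0484). In cholesterol synthesis 0 of 18 genes passed over all genes and 5 were higher adjusted over the list alone (list adjusted p = 0.0611). The block gave 6 higher and 1 lower. Nsdhl read 0.90 ± 0.23 (adjusted p = 0.0554, and 0.0031 with the block), and Dhcr7 1.40 ± 0.37 (0.062, with 0.000156 under the block and 0.00445 without WT array 2).

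In all, 577 of 9097 genes changed in KO polysome RNA, 52 higher and 525 lower. Of these, 520 changed by at least 2-fold. The 52 higher genes became 11, 224 or 25 without WT array 1, 2 or 3 and 16, 15 or 18 without KO array 1, 2 or 3, and array weights gave 751 higher and 853 lower. With arrays centred on their medians (the median change was 0.13) the split was 40 higher and 588 lower of 628, and with the replicate block 1173 higher and 1075 lower of 2248. Without KO array 3 the count was 381, without the 3 arrays of conflicting description 296, and with the deposited, partly unscaled values 0. Most other rises lost their call without single arrays. Timp1, a metalloproteinase inhibitor (1.48 ± 0.31), did so without WT array 1 (adjusted p = 0.0724) or KO array 1 (0.0638) or 2 (0.0746), and Osr2, a transcription factor (1.43 ± 0.28), without WT 1 (0.0652), KO 2 (0.0609) or KO 3 (0.052). Sult1e1, oestrogen sulfotransferase (1.33 ± 0.26), lost it without WT 1 (0.061), KO 1 (0.0515) or KO 2 (0.0506), and Polr2a, an RNA polymerase II subunit (1.23 ± 0.24), without WT 1 (0.0711) or KO 1 (0.0714). Lipg, a lipase (1.42 ± 0.33), lost it without WT 1 (0.119) or 3 (0.0731) or each KO array (0.0829 to 0.131), and Ttyh3 (1.29 ± 0.28) without WT 1 (0.0731) or each KO array (0.0606 to 0.0974). Creb3l1 (1.27 ± 0.32) lost it without WT 1 (0.17) or 3 (0.126) or KO 2 (0.163) or 3 (0.161), and with quantile normalization (0.0903). Mbnl2, a splicing factor (1.28 ± 0.22), kept its call without each array. Other probe sets of Mbnl2 (0.51, adjusted p = 0.414), Sdc4 (0.56, 0.691), Aplp1 (1.68, 0.0761), Lipg (1.13, 0.274) and Polr2a (1.40, 0.291) did not pass.

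In the KO spermatocyte (meiotic) fraction, spermatid transcripts were moderately lower and a small set of genes was clearly higher (n = 4 per genotype). Cyp2c55, a cytochrome P450, was 9.15-fold higher (log2 change 3.19 ± 0.07), from a signal of 47.57 (SD 4.92) to 565.3 (SD 40.3). Fcgr3, an Fc receptor, was 4.74-fold higher (2.25 ± 0.04) and Ptchd3, a sperm membrane protein, higher by 2.20 ± 0.06, with adjusted p of 7.7e-09 to 3.99e-08 for all 3. Tssk6 was 3.85-fold lower (-1.94 ± 0.04), Ubqlnl 3.31-fold lower (-1.73 ± 0.07) and Prm3 2.32-fold lower (-1.22 ± 0.05). Vav2, a guanine nucleotide exchange factor (1.87 ± 0.07), Neo1 (1.44 ± 0.13) and Rab4a (1.37 ± 0.06) also rose. Edem1, a protein of glycoprotein quality control (1.16 ± 0.10), and Bdh1 (1.16 ± 0.06) were also among the largest rises. Clec4g rose by the probe set used (1.52 ± 0.07), but its other probe set went down (-0.83, adjusted p = 0.000164). The largest falls further held Vnn1 (-2.56 ± 0.25), Adam25 (-1.95 ± 0.13), Klk1b8 (-1.74 ± 0.07), Tmem225 (-1.68 ± 0.06) and Grtp1 (-1.61 ± 0.05). Lrrc57 fell too (-1.70 ± 0.09), while its other probe set read 0.23 (adjusted p = 0.428).

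All 17 elongating spermatid markers fell in KO spermatocytes (17 adjusted over the list alone). Their median was -0.91 relative to all genes (camera adjusted p = 1.08e-13, or p = 0.3 with an estimated correlation). Among them were Spata3 (-1.31 ± 0.05), Akap4, the main protein of the fibrous sheath (-0.98 ± 0.05), and Tex37 (-0.98 ± 0.05). In the flagellum list 22 of 34 fell and 1 rose (24 and 1 adjusted over the list alone, adjusted p = 5.11e-10, or p = 0.3 with an estimated correlation). Of 12 spermatid chromatin genes 8 fell (8 adjusted over the list alone, adjusted p = 6.33e-05, or p = 0.48 with an estimated correlation). Prm2 (-0.98 ± 0.07), Tnp2 (-0.89 ± 0.07) and Hmgb4 (-0.57 ± 0.04) were among them. Round spermatid markers fell in 8 of 10 cases (8 adjusted over the list alone, adjusted p = 3.22e-05, or p = 0.3 with an estimated correlation). Cby2 fell by 0.75 and Tssk2 by 0.71 on the log2 scale. With near-identical arrays averaged the flagellum list had 17 lower and 0 higher.

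Ion transport genes fell in 8 of 11 cases (8 adjusted over the list alone, adjusted p = 0.000365, or p = 0.48 with an estimated correlation). They included the channels Catsper1 (-0.63 ± 0.06) and Kcnu1 (-0.56 ± 0.05). Of 25 acrosome genes 11 fell and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 0.000649, or p = 0.48 with an estimated correlation). Capza3 (-0.85 ± 0.04), the hyaluronidase Spam1 (-0.79 ± 0.06) and Acrv1 (-0.38 ± 0.04) were among those that fell. Of 22 energy metabolism genes 7 fell (7 adjusted over the list alone, adjusted p = 0.014, or p = 0.53 with an estimated correlation). Gapdhs (-0.88 ± 0.05) and Aldoart2 (-0.63 ± 0.04) were among these. The block gave 9 lower and 1 higher for ion transport and 14 lower and 2 higher for the acrosome, and averaging near-identical arrays gave 5 and 0 and 7 and 0.

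Leydig cell markers rose in 6 of 8 cases in the KO spermatocyte fraction (6 adjusted over the list alone, camera adjusted p = 0.00202, or p = 0.48 with an estimated correlation). Hsd3b1 (0.96 ± 0.06), the side-chain cleavage enzyme Cyp11a1 (0.60 ± 0.05), Fabp3 (0.44 ± 0.05), Vcam1 (0.43 ± 0.06) and Cyp17a1 (0.38 ± 0.08) were among them. Meiosis genes went both ways, 3 higher and 5 lower of 36 (3 and 4 adjusted over the list alone, list adjusted p = 0.741). Spermatocyte markers had 1 higher and 3 lower of 14 (1 and 3 adjusted over the list alone, list adjusted p = 0.964). Sycp1, a synaptonemal complex protein (-0.25 ± 0.05), and Tex15 (-0.41 ± 0.05) fell. Of 30 chromatoid body genes 5 rose and 4 fell (5 and 4 adjusted over the list alone, list adjusted p = 0.887), and Piwil2, an Argonaute protein of the piRNA pathway, rose by 0.34 ± 0.05. Other changed genes were the ligase Rnf133 (-0.79 ± 0.05), Bcl2l14 (-0.89 ± 0.04), the apoptosis inhibitor Birc2 (0.41 ± 0.04) and the ribosomal protein gene Rps25 (-1.56 ± 0.09). The fit over 24 arrays ended the calls of Cyp11a1 (adjusted p = 0.287), Cyp17a1 (0.344), Vcam1 (0.0525), Acrv1 (0.0666), Piwil2 (0.0695), Tex15 (0.269) and Sycp1 (0.729). With the replicate block 7 meiosis genes were higher and 5 lower, as were 2 and 3 spermatocyte markers and 11 and 5 chromatoid body genes. Averaging near-identical arrays left 0 and 2, 0 and 1, and 1 and 4. The ribosomal protein list passed with the block only (adjusted p = 0.0372, against 0.27).

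In all, 3404 genes changed in KO spermatocytes, 1781 higher and 1623 lower. Only 99 of them changed by at least 2-fold (19 higher, 80 lower). The fit over 24 arrays called 1241 genes (471 higher, 770 lower), and with arrays 1 and 2 and arrays 3 and 4 of each genotype averaged, an alternative added after seeing the data, 1230 genes passed (458 higher, 772 lower). Both turned the balance towards lower genes.

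In KO round spermatids, haploid cells before elongation, lists of spermatid genes were lower, and single genes went both ways. Fcgr3 was 6.67-fold higher (log2 change 2.74 ± 0.06), Ptchd3 6.48-fold higher (2.70 ± 0.08) and Lef1, a transcription factor of Wnt signalling, 4.48-fold higher (2.16 ± 0.07; n = 3 per genotype, adjusted p of 1.23e-06 to 2.09e-06). Dscaml1, a cell adhesion gene, fell from a signal of 2173 (SD 134) to 5.107 (SD 1.84), below the added offset of 16 (-6.70 ± 0.09, adjusted p = 4.42e-08). Ubqlnl was 5.25-fold lower (-2.39 ± 0.09), Tssk6 3.78-fold lower (-1.92 ± 0.10) and the meiotic gene Sycp3 1.94-fold higher (0.95 ± 0.12, 0.000343).

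The other large rises were Asprv1, a protease (4.12 ± 0.52), Slc26a11 (2.47 ± 0.13), Ptpro, a receptor phosphatase (2.29 ± 0.13), and Tnk1, a kinase (2.28 ± 0.17). Gadd45b, a stress-response gene (2.92 ± 0.18), and Nrip2 (2.98 ± 0.56) rose by the probe sets used, while their others read -0.06 (adjusted p = 0.635) and -0.08 (0.694). Rrp9 (2.05 ± 0.64, adjusted p = 0.0246) lost its call without WT array 1 (0.0734) or 2 (0.0621) or KO array 1 (0.0547) or 3 (0.0765), and with quantile normalization (0.054). Large falls were Nat8f4 (-2.90 ± 0.10), Cby3 (-2.78 ± 0.07), Fam131b (-2.74 ± 0.16), Efcab1 (-2.47 ± 0.10), Klk1b8 (-2.46 ± 0.08) and, with other probe sets that did not pass, Lrrc57 (-2.71 ± 0.08; other probe set -0.03, adjusted p = 0.879) and the sugar transporter Slc5a9 (-2.41 ± 0.13; other probe set 0.71, 0.0713).

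All 17 elongating spermatid markers fell in KO round spermatids (17 adjusted over the list alone). Their median was -0.95 relative to all genes (camera adjusted p = 2.7e-07, or p = 0.547 with an estimated correlation). Tex37 (-1.75 ± 0.07), Spata3 (-1.47 ± 0.09), Car2 (-1.33 ± 0.08) and Prm3 (-1.24 ± 0.09) were among them. In the flagellum list 18 of 34 fell and 4 rose (18 and 4 adjusted over the list alone, adjusted p = 6.33e-05, or p = 0.547 with an estimated correlation). Spata18 (-1.50 ± 0.10) and Akap1 (-1.07 ± 0.07) were among those that fell. Round spermatid markers had 6 lower and 1 higher of 10 (7 and 1 adjusted over the list alone, adjusted p = 0.0123, or p = 0.547 with an estimated correlation). Among these, Tssk2 fell (-0.93 ± 0.10). With arrays 1 and 2 averaged the flagellum list had 16 lower and 1 higher, and the round spermatid markers 5 lower and 0 higher.

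Of the energy metabolism genes 10 fell and 4 rose of 22 (10 and 4 adjusted over the list alone, adjusted p = 0.0137, or p = 0.619 with an estimated correlation). Acsbg2 (-1.28 ± 0.06) and Gapdhs (-0.95 ± 0.11) fell. Spermatid chromatin genes had 8 lower and 2 higher of 12 (8 and 2 adjusted over the list alone, adjusted p = 0.0386, or p = 0.625 with an estimated correlation). Of 25 acrosome genes 9 fell and 4 rose (9 and 4 adjusted over the list alone, adjusted p = 0.0368, or p = 0.608 with an estimated correlation). Spam1 (-0.98 ± 0.07) and Prss55 (-0.58 ± 0.06) fell. Of 41 ribosomal protein genes 8 fell and 5 rose (7 and 4 adjusted over the list alone, adjusted p = 0.028, or p = 0.643 with an estimated correlation). Rps25 fell (-1.67 ± 0.10) and Rpl10a rose (0.82 ± 0.08). With quantile normalization the relative medians of the last 2 lists turned to 0.0034 (acrosome) and 0.10 (ribosomal). With arrays 1 and 2 averaged, spermatid chromatin had 3 lower and 2 higher, energy metabolism 7 and 1, and ribosomal proteins 4 and 3, against 14 and 5 with the replicate block for ribosomal proteins.

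Lists for earlier germ cells did not pass in the KO round spermatid fraction, although members of each did. Of 38 meiosis genes 16 rose and 3 fell (16 and 3 adjusted over the list alone, camera adjusted p = 0.234). The kinase Nek2 (0.89 ± 0.07), the cyclin Ccna1 (0.74 ± 0.06) and Sycp1 (0.80 ± 0.08) rose, whereas Syce2, listed for meiosis, fell (-1.05 ± 0.10). Of 14 spermatocyte markers 7 rose and 1 fell (7 and 1 adjusted over the list alone, list adjusted p = 0.492), among them the mismatch repair gene Mlh3 (1.05 ± 0.14). Of 10 spermatogonia markers 8 rose (8 adjusted over the list alone, list adjusted p = 0.0557, and 0.043 with the block). They included Dmrt1, a transcription factor (0.75 ± 0.07), Crabp1 (0.88 ± 0.08) and Stra8, the retinoic acid target of meiotic entry (0.70 ± 0.12). Chromatoid body and piRNA genes had 16 higher and 5 lower of 28 (16 and 5 adjusted over the list alone, list adjusted p = 0.382), with Tdrd9 at 0.81 ± 0.06 and Piwil1 at 0.85 ± 0.07. Relative to all genes, the medians were 0.07 (meiosis), 0.12 (spermatocyte), 0.23 (spermatogonia) and 0.16 (chromatoid body). The block gave 18 higher and 5 lower for meiosis and 7 and 2 for spermatocyte markers, and averaging arrays 1 and 2 gave 14 and 2 for the chromatoid body.

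Spermatid regulators had 12 higher and 6 lower of 30 (12 and 6 adjusted over the list alone, list adjusted p = 0.865), with a mean of 0.13 but a relative median of -0.10. The block gave 13 higher and 10 lower. The RNA-binding protein Elavl1 (1.45 ± 0.10) and the meiotic factor Mybl1 (0.90 ± 0.07) rose. The apoptosis list had 11 higher and 3 lower of 20 (11 and 3 adjusted over the list alone, list adjusted p = 0.49). Birc2 (0.87 ± 0.10) and Rela, an NF-kappaB subunit (0.79 ± 0.08), rose, as did Bcl2l11 (0.93 ± 0.07), whose other probe set read 0.05 (adjusted p = 0.81). Hspa8, a chaperone, rose by 0.92 ± 0.08. Sertoli cell markers fell in 5 of 6 cases in this fraction (5 adjusted over the list alone, adjusted p = 0.00433, or p = 0.48 with an estimated correlation). These were led by Cst9 (-1.25 ± 0.07), Cst12 (-1.12 ± 0.10), Clu (-0.84 ± 0.13) and Aard (-0.69 ± 0.10).

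In all, 5765 genes changed in KO round spermatids, 3727 higher and 2038 lower, with 656 changed by at least 2-fold (285 higher, 371 lower). The median change was 0.15, and with arrays centred on their medians the split turned to 2193 higher and 3133 lower of 5326, so the direction of small changes depends on the scaling. In the fit over 24 arrays the call of Sycp1 was lost (adjusted p = 0.0921).

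**Figure D3:**
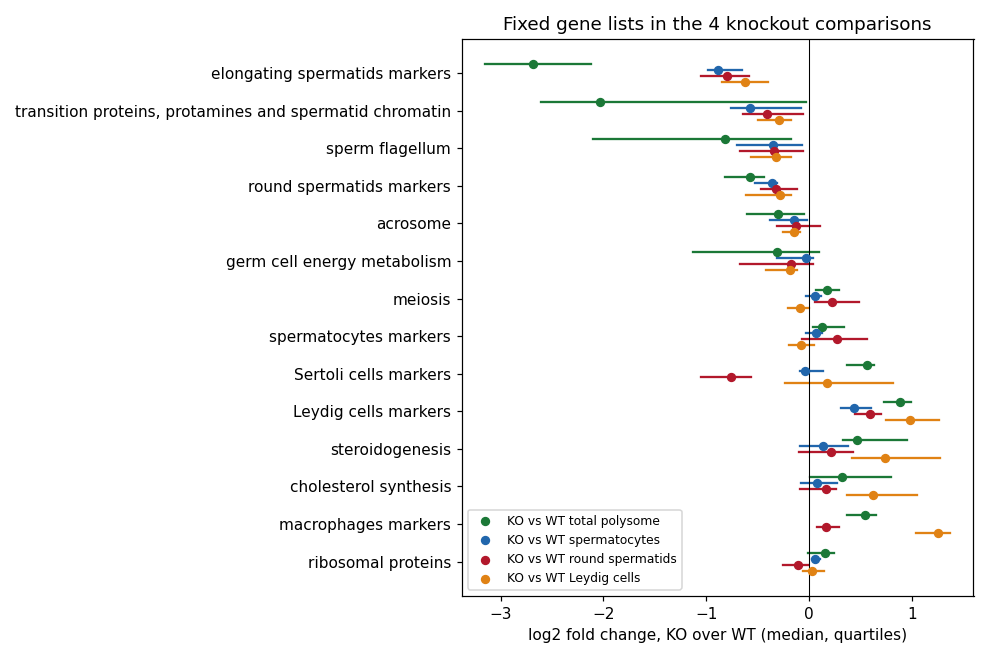
Log2 change between KO and WT (horizontal axis) of 14 fixed gene lists, as the median (point) and quartiles (line) of each list's tested genes, for polysome RNA, spermatocytes, round spermatids and Leydig cells. The elongating spermatid markers lie lowest, with medians of -2.68, -0.88, -0.80 and -0.62, and the Leydig cell markers lie above 0 in all 4 comparisons.

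In the KO Leydig cell fraction, genes of steroid synthesis, cholesterol synthesis and macrophages were higher and spermatid genes were lower. Hsd3b1 was 3.11-fold higher (log2 change 1.64 ± 0.02; signal 2954, SD 36.5, to 9227, SD 92.6), Hsd17b3, which makes testosterone, 2.62-fold higher (1.39 ± 0.03), Cyp11a1 2.45-fold higher (1.29 ± 0.03) and Msmo1, a sterol oxidase, 2.66-fold higher (1.41 ± 0.02; n = 2 per genotype, adjusted p of 2.38e-05 to 2.6e-05). Serpina3n, a serine protease inhibitor, was 11.9-fold higher (3.57 ± 0.04) and Ccdc80, a matrix protein, 8.72-fold higher (3.12 ± 0.03). Ubqlnl was 4.23-fold lower (-2.08 ± 0.03) and Tssk6 2.93-fold lower (-1.55 ± 0.02).

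All 9 Leydig cell markers rose (9 adjusted over the list alone). Their median was 0.99 relative to all genes (camera adjusted p = 0.000279, or p = 0.48 with an estimated correlation), and Vcam1 (1.13 ± 0.02) and Fabp3 (0.80 ± 0.02) were among them. Of 15 steroidogenesis genes 12 rose and 2 fell (12 and 2 adjusted over the list alone, adjusted p = 0.00333, or p = 0.48 with an estimated correlation), with Hsd17b11 at 1.55 ± 0.03. Of 19 cholesterol synthesis genes 16 rose and 1 fell (16 and 1 adjusted over the list alone, adjusted p = 0.000178, or p = 0.48 with an estimated correlation). Nsdhl (1.31 ± 0.03), Ebp (1.26 ± 0.02) and Tm7sf2 (1.06 ± 0.02) rose. Macrophage markers rose in 10 of 11 cases and fell in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.00219, or p = 0.48 with an estimated correlation). The receptor Csf1r (1.43 ± 0.02), the complement genes C1qa (1.42 ± 0.03) and C1qb (1.13 ± 0.02), and lysozyme Lyz2 (1.25 ± 0.02) were among them.

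Other large rises here were Cd52 (2.31 ± 0.07), the class II antigen gene H2-Aa (2.30 ± 0.03), Lrg1 (2.18 ± 0.03), Serpinb1a (2.17 ± 0.07) and the chemokine Ccl8 (2.16 ± 0.04). Tspan4 (2.16 ± 0.11), the prostacyclin synthase Ptgis (2.14 ± 0.06) and Ptchd3 (2.14 ± 0.03) followed. The receptor gene Kit rose by 1.65 ± 0.02 and the immediate early genes Ier3 and Fos by 1.94 ± 0.05 and 1.40 ± 0.02. Xbp1 of the unfolded protein response rose by 1.07 ± 0.02 and the NF-kappaB inhibitor Nfkbia by 1.05 ± 0.03. Their heat shock (11 higher, 9 lower, list adjusted p = 0.433), apoptosis (12, 5, 0.242) and spermatogonia (1, 2, 0.994) lists did not pass.

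Germ cell genes were abundant in this fraction. The protamine Prm1 had a signal of 20600 (SD 351) in WT and 15570 (SD 177) in KO, Tnp1 21000 (SD 225) and 17150 (SD 81.3), and Sycp3 6586 (SD 66.9) and 7119 (SD 15.9). In KO, 33 of 34 flagellum genes fell (33 adjusted over the list alone, camera adjusted p = 6.38e-08, or p = 0.547 with an estimated correlation). All 17 elongating spermatid markers did too (17 adjusted over the list alone, adjusted p = 6.38e-06, or p = 0.547 with an estimated correlation). So did 21 of 22 energy metabolism genes (21 adjusted over the list alone, adjusted p = 4.73e-05, or p = 0.48 with an estimated correlation). Among them were Spata18 (-1.45 ± 0.02), Tex37 (-1.32 ± 0.02), Prm3 (-1.28 ± 0.02), Spata3 (-1.25 ± 0.02), Acsbg2 (-1.43 ± 0.02) and Gapdhs (-0.94 ± 0.02).

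Further lists were lower in the KO Leydig fraction. Spermatid chromatin had 10 of 11 lower (10 adjusted over the list alone, adjusted p = 0.00335, or p = 0.496 with an estimated correlation). Acrosome genes had 19 lower and 2 higher of 25 (19 and 3 adjusted over the list alone, adjusted p = 0.0052, or p = 0.547 with an estimated correlation). Ubiquitin and proteasome genes had 27 lower and 6 higher of 42 (27 and 6 adjusted over the list alone, adjusted p = 0.00539, or p = 0.48 with an estimated correlation), with Rnf133 at -1.18 ± 0.02. Spermatid regulators had 22 lower and 2 higher of 30 (22 and 2 adjusted over the list alone, adjusted p = 0.00795, or p = 0.547 with an estimated correlation). Ion transport had 9 lower and 1 higher of 11 (9 and 1 adjusted over the list alone, adjusted p = 0.00911, or p = 0.484 with an estimated correlation). Round spermatid markers had 8 lower of 10, and 8 lower with 1 higher adjusted over the list alone (adjusted p = 0.0123, or p = 0.57 with an estimated correlation). Meiosis genes had 20 lower and 3 higher of 33 (19 and 3 adjusted over the list alone, adjusted p = 0.0456, or p = 0.547 with an estimated correlation), with Syce2 at -0.64 ± 0.02.

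Sertoli cell markers split, with 5 higher and 4 lower of 9 (5 and 4 adjusted over the list alone, camera adjusted p = 0.592). The protease Ctsl rose (0.89 ± 0.02) and Cst12 fell (-0.51 ± 0.02). The largest falls held Efcab1 (-2.46 ± 0.07), Klk1b8 (-2.34 ± 0.05), Cby3 (-2.15 ± 0.03), Slc5a9 (-1.96 ± 0.06) and Rps25 (-1.93 ± 0.02). Lrrc57 fell as well (-2.33 ± 0.02), against 0.59 for its other probe set (adjusted p = 0.0166). The ribosomal protein gene Rps4x rose by 1.32 ± 0.02. In all, 7087 genes changed, 3510 higher and 3577 lower, and 785 by at least 2-fold (606 higher, 179 lower). With median-centred arrays the split was 2881 higher and 4396 lower of 7277. The 2 arrays of each genotype were nearly identical. In the fit over 24 arrays 2115 genes passed (1290 higher, 825 lower) and the calls of Cyp11a1 (adjusted p = 0.0539), Nfkbia (0.0672) and Cst12 (0.0619) were lost.

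**Figure D4:**
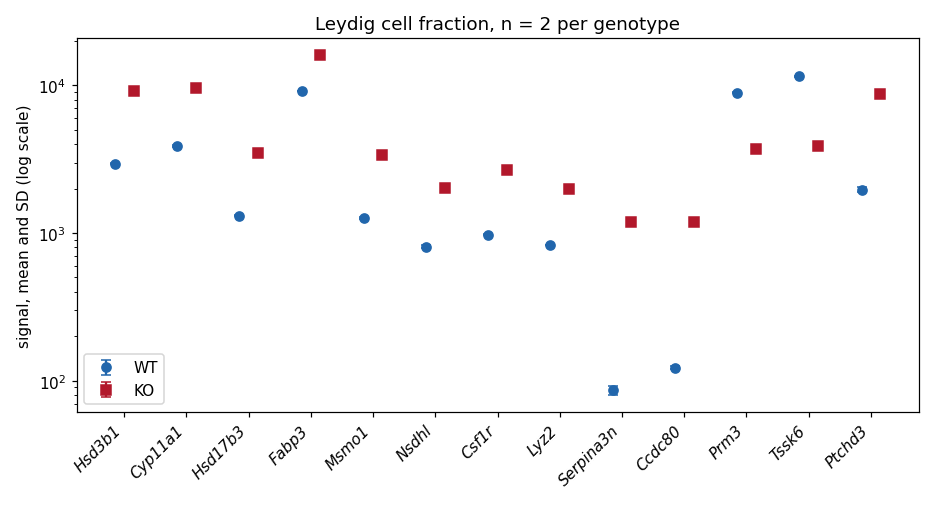
Signal of 13 genes in the Leydig cell fraction (log axis), WT circles and KO squares with SDs, n = 2 per genotype. Hsd3b1 rises from 2954 to 9227 and Serpina3n from 85.79 to 1196, while Prm3 falls from 8955 to 3690.

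GRTH IP was set against IgG IP to find polysomal transcripts bound by the helicase. The replicates were uneven. Relative to the trimmed mean, the bioB control read 5.45 and 69.9 on GRTH arrays 1 and 2, and 2.51 and 18.1 for IgG. Other arrays read 0.287 to 6.26. No gene passed. With limma, 0 of 9097 genes were called, with 364 at an unadjusted p under 0.05 and a smallest adjusted p of 0.977 (n = 2 per group). Ddx25 was not detectably enriched (-0.39 ± 0.59, adjusted p = 0.977), with signals of 11450 (SD 3550) in the GRTH IP and 14640 (SD 677) in the IgG IP. The genes with the smallest p that were higher in the GRTH IP were Slc25a40 (2.87 ± 0.61), Rapgef2 (2.28 ± 0.58), Shisa3 (2.25 ± 0.58), the mitochondrial ND5 (4.19 ± 1.11) and the stem cell factor gene Kitl (2.57 ± 0.71). Another probe set of Kitl read -0.75 (adjusted p = 0.999). Those lower were Tubg1 (-3.56 ± 0.87), Lgmn (-3.14 ± 0.79), Aldh2 (-2.51 ± 0.65), Rbmxl2 (-3.55 ± 0.95) and Ddx49 (-2.26 ± 0.61). Without IgG array 1, 12 genes passed, among them Slc25a40 (adjusted p = 0.0376), Tubg1 (0.0125), Lgmn (0.00248) and Rbmxl2 (0.00477). Without IgG array 2, 21 passed, among them ND5 (2.37e-08), Kitl (0.0145), Tubg1 (0.0152) and Rbmxl2 (0.0329).

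Lists shifted between the IP groups although 0 of their members passed, over all genes or adjusted over the list alone. Spermatocyte markers lay higher in the GRTH IP (relative median 0.56, camera adjusted p = 0.0148, or p = 0.569 with an estimated correlation), with Tex12 at 2.29 ± 0.64 and Sycp2 at 1.69 ± 0.61. Ribosomal protein genes did too (0.32, adjusted p = 0.0346, or p = 0.765 with an estimated correlation), but lay at -0.24 without IgG array 2 and at 0.94 without IgG array 1. The flagellum list lay lower (-0.57, adjusted p = 0.00176, or p = 0.547 with an estimated correlation), with Tekt4 at -1.31 ± 0.58 and Spag4 at -1.35 ± 0.64. Round spermatid markers (-0.71, adjusted p = 0.00308, or p = 0.547 with an estimated correlation), with Cby2 at -1.42 ± 0.58, and ion transport (-0.61, adjusted p = 0.0177, or p = 0.536 with an estimated correlation) were lower too. Leydig cell markers were lower (-0.84, adjusted p = 0.00276, or p = 0.48 with an estimated correlation), with Cyp11a1 at -1.70 ± 0.58 and Ces1d at -1.64 ± 0.59. So were steroidogenesis (-0.53, adjusted p = 0.00539, or p = 0.48 with an estimated correlation) and macrophage markers (-0.68, adjusted p = 0.0474, or p = 0.575 with an estimated correlation). The spermatid regulators Qk (1.68 ± 0.59), Cpeb2 (1.67 ± 0.60) and Boll (1.57 ± 0.59) did not pass (limma adjusted p = 0.977 for each). Neither did the protamine genes Prm3 (1.10 ± 0.61) and Prm1 (0.87 ± 0.95). Prm1 read -0.17 without IgG array 1 and -0.53 without GRTH array 2.

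Genes at least 2-fold higher on each GRTH IP array than on each IgG IP array were then set against genes lower in KO polysome RNA. Of 8230 genes tested in both, 76 were that much higher in the IP without passing a test and 523 were lower in KO polysome RNA. Leaving out 1 IP array changed the 76 to 241 (without IgG 1), 783 (IgG 2), 241 (GRTH 1) or 312 (GRTH 2). In both sets were 0 genes against 4.83 expected (odds ratio 0, 95% confidence interval 0 to 0.728, Fisher's exact p = 0.0148). Genes are not independent replicates, so this and the following exact tests and intervals overstate certainty. The sensitivity of the 2-fold rule was not simulated and its 76 genes passed no test, so no depletion of bound transcripts is concluded. At 1.5-fold on each array, 7 of 269 genes were in both against 17.1 expected (odds ratio 0.386, interval 0.153 to 0.812, exact p = 0.00718). Taking the 500 genes whose group means differed by 2-fold, a definition added after seeing the data, 8 were in both against 31.8 expected (odds ratio 0.228, interval 0.0972 to 0.456, exact p = 3.43e-07). With the first definition the p rose above 0.05 without IgG array 1 (12 shared genes, odds ratio 0.767, exact p = 0.501), GRTH array 1 (0.498, exact p = 0.0588), WT polysome array 1 (exact p = 0.0507) and KO polysome array 1 (0.0507), 2 (0.0525) or 3 (0.0812).

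WT round spermatids were set against WT spermatocytes to describe the normal change between stages. Spermatid genes were strongly higher. Spatc1 was 12.8-fold higher (log2 change 3.68 ± 0.09), Nqo2, a quinone reductase, 13.9-fold higher (3.80 ± 0.07), Tex37 9.09-fold higher (3.18 ± 0.06) and Prm3 5.84-fold higher (2.55 ± 0.08; n = 3 and 4, adjusted p of 1.91e-09 to 7.02e-09). Among the genes that fell, Piwil1 was 13.1-fold lower (-3.72 ± 0.06), Tdrd5 11.8-fold lower (-3.56 ± 0.07), Id4 16.5-fold lower (-4.05 ± 0.12) and the kinase Cdk2 9.51-fold lower (-3.25 ± 0.10). Ddx25 was alike in both stages within error (0.17 ± 0.10, adjusted p = 0.144), and its sign turned with quantile normalization (-0.46, 1.05e-05).

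All 17 elongating spermatid markers rose from spermatocytes to round spermatids (17 adjusted over the list alone, relative median 2.15). Their camera adjusted p was 6.38e-06, or p = 0.547 with an estimated correlation, and Spata3 read 2.65 ± 0.09. All 10 round spermatid markers rose as well (10 adjusted over the list alone, adjusted p = 0.000194, or p = 0.48 with an estimated correlation). Izumo1, the sperm-egg fusion protein (1.80 ± 0.07), Cby2 (2.57 ± 0.07) and Tssk1 (1.94 ± 0.06) were among them. Of the flagellum genes 30 rose and 4 fell of 34 (30 and 4 adjusted over the list alone, adjusted p = 4.02e-06, or p = 0.48 with an estimated correlation). Akap1 (2.69 ± 0.07) and Spag4 (2.20 ± 0.06) rose. Of the acrosome genes 18 rose and 6 fell of 25 (18 and 6 adjusted over the list alone, adjusted p = 0.0018, or p = 0.484 with an estimated correlation), including Prss55 (2.78 ± 0.05) and Spaca7 (2.13 ± 0.05).

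Spermatid chromatin had 10 higher and 2 lower of 12 (10 and 2 adjusted over the list alone, adjusted p = 0.0192, or p = 0.575 with an estimated correlation). The linker histone H1f7 rose (2.25 ± 0.09) and Hmgb2 fell (-2.04 ± 0.10). Ubiquitin and proteasome genes had 26 higher and 15 lower of 43 (26 and 15 adjusted over the list alone, adjusted p = 0.0265, or p = 0.53 with an estimated correlation). Rnf133 rose (3.03 ± 0.07) and Siah1a fell (-2.84 ± 0.06). Gapdhs (2.06 ± 0.09), Acsbg2 (2.68 ± 0.08), Hspa1l (3.09 ± 0.07) and Ace, which has a germ cell form (2.67 ± 0.07), rose. Cpeb2 (-3.21 ± 0.08), Tdrd1 (-3.01 ± 0.06), Fos (-2.57 ± 0.09) and Rpl10a (-1.61 ± 0.06) fell.

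Chromatoid body and piRNA genes had 17 lower and 8 higher of 29 (17 and 8 adjusted over the list alone, camera adjusted p = 0.169). Meiosis genes had 20 lower and 11 higher of 38 (20 and 11 adjusted over the list alone, list adjusted p = 0.638). Sycp2 fell (-1.98 ± 0.08), but Tex15 (1.64 ± 0.06) and Syce2 (2.00 ± 0.08) rose. Leydig cell markers fell in 8 of 9 cases and rose in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.0456, or p = 0.48 with an estimated correlation and 0.062 with the block). Cyp11a1 (-3.29 ± 0.11), Fabp3 (-3.11 ± 0.10) and Cyp17a1 (-3.01 ± 0.10) fell. Sertoli cell markers rose in 5 of 6 cases (5 adjusted over the list alone, adjusted p = 0.0275, or p = 0.48 with an estimated correlation), with Cst12 at 1.96 ± 0.07. Macrophage markers rose in 4 of 4 (4 adjusted over the list alone, adjusted p = 0.0148, or p = 0.48 with an estimated correlation), with C1qb at 3.39 ± 0.09, Aif1 at 2.55 ± 0.10 and Csf1r at 2.03 ± 0.08.

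Other large rises were Slc5a9 (3.71 ± 0.21), Cby3 (3.63 ± 0.07), Lrrc57 (3.52 ± 0.06), Paqr5 (3.44 ± 0.06) and Klk1b8 (3.44 ± 0.10). Other large falls were Kbtbd6 (-4.12 ± 0.14), Ccp110, a centriolar protein (-3.89 ± 0.06), Fbxo3 (-3.75 ± 0.11), Sap30 (-3.74 ± 0.10) and Pim3 (-3.64 ± 0.27). In all, 7929 genes differed, 3289 higher and 4640 lower in round spermatids. The median change was -0.23, and with median-centred arrays the split was 4144 higher and 3666 lower of 7810.

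The KO effect was compared between round spermatids and spermatocytes with an interaction term. Single meiotic and piRNA genes had a more positive KO effect in round spermatids (3 or 4 arrays per group), but the lists for meiosis (adjusted p = 0.254), chromatoid body and piRNA (0.103) and spermatogonia (0.14) did not pass. Sycp1 differed by 1.05 ± 0.09, Ccna1 by 0.80 ± 0.07, Tdrd1 by 1.08 ± 0.10 and Mybl1 by 1.23 ± 0.10 on the log2 scale (limma adjusted p of 1.65e-06 to 4.09e-06). Lef1 (1.84 ± 0.11) and the decapping cofactor Edc4 (1.59 ± 0.09) differed in the same direction, and Plekha3 (-1.85 ± 0.13) and Efcab1 (-1.80 ± 0.16) in the opposite one. Nrip2 (3.75 ± 0.75), Gadd45b (2.19 ± 0.21), Rab6b (2.73 ± 0.41), Slc5a9 (-2.20 ± 0.26) and Habp4 (-1.62 ± 0.09) also passed. Other probe sets read 0.30 for Gadd45b (adjusted p = 0.166), -0.43 for Rab6b (0.263), 0.30 for Slc5a9 (0.621) and 0.11 for Habp4 (0.762). Ddx25 did not pass (0.29 ± 0.13, adjusted p = 0.0741). It did with quantile normalization (0.81, 4.6e-06), with the replicate block (0.0411) and without WT round spermatid array 1 (0.0358), KO round spermatid array 3 (0.0423) or WT spermatocyte array 4 (0.0269).

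Sertoli cell markers had a lower KO effect in round spermatids, 5 of 6 passing (5 adjusted over the list alone). Their relative median was -0.82 (camera adjusted p = 0.000413, or p = 0.3 with an estimated correlation), with Clu at -1.25 ± 0.13 and Cst9 at -0.76 ± 0.10. Ribosomal protein genes had 8 lower and 3 higher of 40, with 8 and 3 adjusted over the list alone and 22 and 4 with the block. Their relative median was -0.30 (adjusted p = 0.00146, or p = 0.595 with an estimated correlation). Rps15 read -0.43 ± 0.10, and its other probe set -0.13 (adjusted p = 0.315). Energy metabolism had 3 lower and 3 higher of 22, with 1 and 2 adjusted over the list alone and 10 and 4 with the block (-0.28, adjusted p = 0.0456, or p = 0.619 with an estimated correlation). With quantile normalization these relative medians turned to 0.015 (ribosomal) and 0.10 (energy). Chromatoid body genes had 14 higher and 2 lower of 29 (15 and 3 adjusted over the list alone, list adjusted p = 0.103) and elongating spermatid markers 2 higher and 1 lower of 17 (1 and 1 adjusted over the list alone, list adjusted p = 0.26). With the block these were 17 and 5, and 5 and 4. Averaging near-identical arrays left 3 lower Sertoli cell markers, 1 lower and 1 higher ribosomal, 0 energy metabolism, 7 higher and 0 lower chromatoid body genes, and 1 higher and 1 lower elongating spermatid markers. In all, 4186 genes differed, 2941 positive and 1245 negative. The median was 0.14, and with median-centred arrays 1306 were positive and 2437 negative of 3743. The fit over 24 arrays called 1723 genes, without Sycp1 (adjusted p = 0.152), and averaging left 1737.

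The KO effect in total polysome RNA was likewise compared with that in round spermatids (3 arrays per group). The polysome RNA came from the total testis and the other RNA from a cell fraction. Differences therefore cannot be told apart from different mixtures of cells. Late spermatid genes fell further in polysome RNA. The effects differed by -2.63 ± 0.41 for Oaz3 (limma adjusted p = 0.00813), -2.61 ± 0.33 for Smcp (0.00318), -2.33 ± 0.45 for Prm2 (0.0192) and -2.32 ± 0.37 for Odf1, an outer dense fibre protein (0.0089). Other probe sets read -2.12 for Oaz3 (adjusted p = 0.0715) and -1.70 for Odf1 (0.137). Ddx25 differed by -2.37 ± 0.29 (0.00318). Ptchd3 (-3.38 ± 0.22, 1.85e-05) and Fcgr3 (-3.00 ± 0.29, 0.000585), which rose in KO round spermatids, did not pass in polysome RNA (-0.69 ± 0.22, adjusted p = 0.122, and -0.26 ± 0.27, 0.636).

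Of 17 elongating spermatid markers 11 differed downwards (15 adjusted over the list alone). Their relative median was -1.65 (camera adjusted p = 5.25e-13, or p = 0.48 with an estimated correlation). Spermatid chromatin had 6 of 12 lower (7 adjusted over the list alone, median -1.41, adjusted p = 5.33e-05, or p = 0.48 with an estimated correlation). The flagellum list had 6 of 34 lower, 13 adjusted over the list alone and 12 with the block (-0.29, adjusted p = 0.000178, or p = 0.484 with an estimated correlation). Sertoli cell markers had 3 of 14 higher, 8 adjusted over the list alone and 9 with the block (1.17, adjusted p = 5.58e-10, or p = 0.48 with an estimated correlation). These were Cst12 (1.68 ± 0.28, 0.0104), Cst9 (1.61 ± 0.26, 0.00862) and Tsx (1.73 ± 0.40, 0.0398).

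Further lists were called although no member passed over all genes. Ribosomal proteins had 0 of 39 (0 adjusted over the list alone, median 0.36, adjusted p = 0.000192, or p = 0.547 with an estimated correlation). Steroidogenesis had 0 of 15 (0 adjusted over the list alone, median 0.46, adjusted p = 0.0328, or p = 0.524 with an estimated correlation). Cholesterol synthesis had 0 of 15 (0 adjusted over the list alone, median 0.17, adjusted p = 0.0368, or p = 0.48 with an estimated correlation). Leydig cell markers had 0 of 9, with 1 higher adjusted over the list alone (median 0.60, adjusted p = 0.0474, or p = 0.547 with an estimated correlation). The replicate block gave 1, 2, 2 and 1 higher genes in this order, and 1 lower Leydig cell marker. With it the lists for macrophages (adjusted p = 0.00726, against 0.122), chromatoid body and piRNA (0.0274, against 0.0557) and spermatid regulators (0.0389, against 0.078) passed too.

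In all, 254 genes differed between polysome RNA and round spermatids in their KO effect, 49 positive and 205 negative. The median was -0.14, and with median-centred arrays 80 were positive and 97 negative of 177. The replicate block gave 1402 (367 positive, 1035 negative). Averaging round spermatid arrays 1 and 2 left 5 genes and 0 members of any list. Leaving out WT polysome array 2 gave 726, and leaving out a round spermatid array 71 to 113. Dmpk, a muscle kinase (1.87 ± 0.42, adjusted p = 0.0383), lost its call without each KO polysome array (0.0508 to 0.0661) or round spermatid array in turn (0.07 to 0.106). Tsx lost it with an offset of 64 (0.0715), without WT polysome array 1 (0.0753) or 3 (0.0584), KO polysome array 2 (0.0742) or 3 (0.0699), or each round spermatid array in turn (0.089 to 0.108). Prm2 lost it without WT round spermatid array 2 or 3 or KO round spermatid array 1 or 2 (0.0572 to 0.0653), and Hmbox1, a homeobox gene (1.72 ± 0.31, 0.0138), without WT round spermatid array 2 (0.0545). Another probe set of Hmbox1 read 0.37 (adjusted p = 0.735).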

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

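The counts over other splits of the samples were planned, and every test below that weighs an explanation for a pattern was chosen only after the result was seen.

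Late spermatid transcripts were lower in KO total polysome RNA and in the KO cell fractions. Rescaling of the 4 polysome arrays is argued against as the whole cause, since genes at least 2-fold lower between the arrays numbered 1 and 2 had a median log2 change of -2.36 (314 genes, quartiles -2.87 to -1.85) between the arrays numbered 3, which the authors had scaled. Spermatid RNA carried into the spermatocyte fraction stays open as a cause of the falls seen there. For 337 genes lower in KO polysome RNA, WT round spermatids hold at least 4-fold more than WT spermatocytes. Over these genes the KO effects of the fractions differed by a median of -0.43 (quartiles -0.67 to -0.22), against 0.14 over all genes tested. Carried RNA alone would give a difference near 0, and a fall within spermatocytes could give such values too, so they do not decide. Fewer late spermatids in the KO testis cannot be told apart from lower transcript levels per cell, because cell numbers were not analysed here; 93.1% of the 525 genes lower in polysome RNA had a negative log2 change in all 3 fractions, past the threshold or not, against 14.7% of other genes. An effect of the helicase on these transcripts stays open as well, as a hypothesis.

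Genes of Leydig cells were higher in the KO Leydig fraction. A lower share of germ cells would raise markers of all somatic cells alike. The mean log2 changes of Leydig and Sertoli cell markers differed by 0.731 (SDs 0.38 and 0.56, 18 genes, exact permutation p = 0.00675). This cannot decide the question, since most tested Sertoli cell markers were themselves higher in WT round spermatids than in WT spermatocytes. Macrophage markers, not part of the test, rose beside the Leydig cell markers (medians relative to all genes 1.26 and 0.99). Normalization between arrays is argued against by a median of 0.981 (9 genes, quartiles 0.79 to 1.29) after quantile normalization, against 0.979 before. A lower share of germ cells, and so a larger share of Leydig cells and macrophages, in the KO fraction stays open. More transcript per Leydig cell stays open too, as an untested hypothesis.

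Single meiotic genes such as Sycp3 were higher in the KO round spermatid fraction, although the meiosis list did not pass (adjusted p = 0.234). More spermatocyte RNA in that fraction is a candidate explanation: of 360 genes with a WT spermatocyte signal over 1000 and at least 4-fold above WT round spermatids, 90.8% were higher in KO round spermatids, and the spermatocyte share that each would imply had a median of 9.06% (quartiles 4.35 to 15%). The median change over all genes was also positive (0.15). The 360 were chosen with the same WT round spermatid arrays that enter the change, which favours a rise. Normalization between arrays is argued against as the whole cause, since the median change of such genes less that of all genes was 0.332 after quantile normalization, against 0.438 before. A change of these transcripts within round spermatids was not tested and stays open.

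Other splits of the same arrays were fitted in the same way. For spermatocytes 1 of 35 splits gave as many genes as the real 3404, and the highest other split, which sets arrays 1 and 2 of both genotypes against arrays 3 and 4, gave 139. Splits that ignore the numbered pairs and the near-identical arrays treat them as independent, however, and the 7 other splits that part all 4 numbered pairs (highest 0) are too few for a share under 0.05. For WT round spermatids against WT spermatocytes 1 of 35 gave as many as 7929 and the highest other gave 0, where near-identical arrays likewise leave fewer independent splits than 35. For polysome RNA (real 577, highest other 0) and round spermatids (real 5765, highest other 0), 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. For the difference of KO effects between round spermatids and spermatocytes 6 of 100 drawn splits (of 700) gave as many as 4186. The highest other gave 6075, all 5 others as large leave the genotypes of a source whole, and of 90 splits that mix both sources the highest gave 3. For polysome RNA against round spermatids 11 of 100 (of 200) gave as many as 254. The highest other gave 3713, 10 of them leave a source whole, and the highest of 79 mixed splits gave 0. Splits that leave a source whole keep its KO effect in the contrast, a structure of the samples. These 2 shares therefore neither exclude chance nor show it.

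The KO effect differed between round spermatids and spermatocytes for 4186 genes by the interaction test. Positive differences included Nrip2 (3.75), Rab6b (2.73), Gadd45b (2.19), Lef1 (1.84), Edc4 (1.59), Mybl1 (1.23), Tdrd1 (1.08), Sycp1 (1.05) and Ccna1 (0.80), and negative ones Slc5a9 (-2.20), Plekha3 (-1.85), Efcab1 (-1.80), Habp4 (-1.62), Clu (-1.25), Cst9 (-0.76) and Rps15 (-0.43), on the log2 scale. Lists that differed were Sertoli cell markers (-0.82 relative to all genes), ribosomal proteins (-0.30) and energy metabolism (-0.28), which did not pass with an estimated correlation (adjusted p = 0.3, 0.595 and 0.619). With quantile normalization the ribosomal and energy medians turned to 0.015 and 0.10, and averaging near-identical arrays left 1737 genes.

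Between polysome RNA and round spermatids the KO effect differed for 254 genes by the same kind of test, confounded with the testis cell mixture. Differences were negative for Ptchd3 (-3.38), Fcgr3 (-3.00), Oaz3 (-2.63), Smcp (-2.61), Ddx25 (-2.37), Prm2 (-2.33) and Odf1 (-2.32) and positive for Dmpk (1.87), Tsx (1.73), Hmbox1 (1.72), Cst12 (1.68) and Cst9 (1.61). Lists that differed, relative to all genes, were elongating spermatid markers (-1.65), spermatid chromatin (-1.41), flagellum (-0.29), Sertoli cell markers (1.17), Leydig cell markers (0.60), steroidogenesis (0.46), ribosomal proteins (0.36) and cholesterol synthesis (0.17). With an estimated correlation none passed (adjusted p = 0.48 to 0.547), and averaging near-identical arrays left 5 genes and 0 members of any list.

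In the spermatocyte groups of 4, a sample lay far from the other 3 for 8 of 170 values tested, where chance alone gives about 1 in 20. The gap, as a share of the whole range, was 0.925 for Slc5a9, 0.861 for Syce2, 0.835 for Siah1a and 0.868 for the acrosome list's median in WT, and 0.846 for Rab4a, 0.861 for Spam1, 0.913 for the apoptosis list's median and 0.881 for the spermatocyte markers' median in KO.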

How the results depend on the processing

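The values as deposited, the subsets of polysome arrays, the averages, blocks and subsets of near-identical arrays and the overlap by group means were chosen only after the result was seen; all other settings were planned. Of the alternatives for 305 gene values, 3489 kept direction and side of the threshold, 42 newly passed, 89 no longer passed and 15 reversed; for 68 list calls these were 788 kept, 172 no longer passing and 5 reversed. Signal near background and the noise of the polysome and IP arrays limit what small changes can be seen. Where no reason is given, the cause was not tested.

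Counts moved by over 1.5 times as follows. With the filter at the 75th percentile, which tests fewer genes, 1818 genes passed in spermatocytes, 3112 in round spermatids, 3859 in Leydig cells, 4030 between WT stages and 2516 for round spermatids minus spermatocytes. All probe sets gave 5463, 9884, 14455, 17632 and 7074 in the same order, more features being tested, and 122 for polysome minus round spermatids; the added 2-fold limit gave 99, 656, 785, 4123 and 240. The fit over 24 arrays gave 3137 in polysome RNA, 1241 in spermatocytes, 2115 in Leydig cells, 1723 for round spermatids minus spermatocytes and 1589 for polysome minus round spermatids. The replicate block, which removes spread shared by same-numbered arrays, gave 2248 in polysome RNA, 65 in the IP and 1402 for polysome minus round spermatids. For the IP and Leydig arrays the numbers are not shown to pair the samples, having 2 pairs with deviations correlated at 0.434 and 0.0277. Outside the IP, and apart from the values given, the block changed no call of a named gene or list.

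No filter gave 378 (polysome) and 72 (polysome minus round spermatids), array weights 1604 and 1131, arrays of agreeing labels 296 and 1652 (12 in the IP), and the unscaled values 0 and 0, since the 4 unscaled arrays then differ from the rest by their level. Polysome arrays 1 and 2 alone gave 322. For polysome minus round spermatids, quantile normalization gave 436, an adjusted p under 0.10 gave 564, leaving out both polysome arrays numbered 2 gave 739 and averaging near-identical arrays 5; averaging also gave 1230 in spermatocytes and 1737 for round spermatids minus spermatocytes.

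Leaving out 1 array at a time gave 381 to 752 genes in polysome RNA (381 without KO 3), 2923 to 3108 in spermatocytes, 4997 to 6100 in round spermatids, 6185 to 6635 in Leydig cells, 0 to 21 in the IP (12 without IgG 1, 21 without IgG 2), 7692 to 7985 between WT stages, 3728 to 4495 for round spermatids minus spermatocytes and 71 to 726 for polysome minus round spermatids (726 without WT polysome 2). The overlap's odds ratio ran from 0 to 0.767, and for genes higher in KO polysome RNA it was 0 (exact p = 1); taking IP genes by adjusted p gave no genes and so no value. List calls numbered 0 with an estimated correlation, 105 with fry, and 62 to 71 without each array.

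Directions reversed with quantile normalization for the acrosome (0.0034) and ribosomal (0.10) lists in round spermatids, for energy metabolism (0.10) and ribosomal proteins (0.015) in round spermatids minus spermatocytes, and for Ddx25 between WT stages (-0.46). Ribosomal proteins in the IP read -0.24 without IgG array 2 and 0.94 without IgG array 1. Prm1 in the IP read -0.17 without IgG array 1, -0.53 without GRTH array 2 and 2.27 without GRTH array 1. Other probe sets reversed Lrrc57 (0.032 in polysome RNA, 0.23 in spermatocytes, 0.59 in Leydig cells), Gpd2 (0.056, polysome), Clec4g (-0.83, spermatocytes), Nrip2 (-0.083), Gadd45b (-0.058) and Slc5a9 (0.71) in round spermatids, Kitl (-0.75, IP), and Rab6b (-0.43), Slc5a9 (0.30) and Habp4 (0.11) in round spermatids minus spermatocytes.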

Other observations

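All tests in this part were chosen only after the result was seen. Across the 7433 genes tested in all 4 KO comparisons, 412 were lower in all 4, and 16 of these were elongating spermatid markers. Independent lists would give 8.69, but these lists are not independent, although the comparisons share no arrays. The sources hold much RNA in common: mean log2 signals of WT Leydig cells correlated at 0.969 with WT spermatocytes and at 0.95 with WT polysome RNA. Higher in all 4 were 6 genes, against 0.573 by the same reckoning, with 21 of the 7433 called higher in polysome RNA. They were 4933428M09Rik, Akap2, Edem1, Lrrc61, Trim14 and Ube2c, a ubiquitin-conjugating enzyme of the cell cycle. The KO effects of polysome RNA correlated across genes at r = 0.653 with spermatocytes, 0.713 with round spermatids and 0.632 with Leydig cells, and genes are not independent replicates.

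Markers of endothelium, blood and epididymis had fewer than 3 tested genes in each comparison. Their median signals in WT and KO polysome RNA were 90.3 (SD 18.8) and 104.9 (SD 17.98) for endothelium, 53.1 (SD 12.8) and 35.03 (SD 17.03) for blood, and 59.4 (SD 18.2) and 79.7 (SD 39.5) for epididymis and other tissue (n = 3 each). Tested members were Vwf (365 and 581), Alas2 (298.1 and 359.8), Car3 (404.6 and 646.9) and Adipoq (394.1 and 312.8), and 0 of these passed.

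Rps25, Tmem225 and Dscaml1, singled out after their falls in KO cells were seen, lie 178, 135 and 208 genes from Ddx25 on its chromosome in the gene order of the current RefSeq table. Genes changed at least 2-fold were counted within 50, 100, 250 or 500 genes of Ddx25 in the 4 KO comparisons, and 0 of the 16 Fisher's exact tests passed after adjustment (smallest adjusted p = 0.181). The smallest raw p was 0.0113, in round spermatids within 250 genes, where 20 of 156 neighbours had changed (12.8%, against 7.10% of other genes; odds ratio 1.92, 95% interval 1.13 to 3.11).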
